A study of Mus musculus with 12 samples.

How the data were processed

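Libraries of ribosome-bound mRNA from subcutaneous B16F10 and B16F0 tumours were prepared with a kit named ScriptSeq, per the labels. The authors deposited whole-number read counts per gene symbol for 12 libraries, 7 of B16F10 and 5 of B16F0. The tools cutadapt 1.16, STAR 2.2.1, featureCounts 1.6.0, edgeR and R 3.3.2 and the build mm10 are named per the submitters' processing notes, without their settings. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies may be shared between symbols. The authors' deposited comparison table holds log2 fold changes, mean log2 CPM and p-values written with a decimal comma, which was read as a decimal point. Its 21 row names that match no gene of the count table have the form of calendar dates and were left out. A deposited table of normalized values was not used, because its decimal marks were lost and the size of a value could not be read.

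Groups came from the labels, and the sequencing lane (1, 2 or 6) from the library names in them. Both groups were present on each of the 3 lanes, so the lane entered the fit as a factor. Of 24421 gene symbols 1069 had no count in any library, and 13534 passed the filterByExpr function of edgeR 4.0.16 with its default minimum count of 10 and group as the design. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test in R 4.3.3, with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. The biological coefficient of variation was 0.318. Log2 fold changes are B16F10 over B16F0, and their standard errors are the fold change divided by the square root of F. CPM values use TMM-scaled totals of the tested genes. Library totals ran from 5322510 to 20569186 counts, which limits the precision of genes of few CPM most in B16F10 replicate 1, the shallowest library.

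Before the data were examined, 52 gene lists of cell types and pathways, the rule for named genes and a first set of other settings were fixed. Of the 52 lists 51 had at least 1 tested gene. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry. Genes were named by 3 rules. The first took the 10 highest and 10 lowest fold changes among called genes with a mean of at least 5 CPM and the same direction in each lane, without predicted genes. The second took up to 4 members with the smallest p of each list with a called member and 2 of a called list without one. The third took 10 genes chosen in advance for the tagged cell, the tumour cell and the Slit and Tlr3 genes. Coordinates were taken from GENCODE release M21 on the same build, in which 23363 of the symbols (95.7%) were found. Library measures were compared by exact permutation over all 792 splits of the 12 libraries, and over the 180 splits that keep the groups' numbers within each lane, with two-sided p. Background reads were taken as the CPM summed over 1498 olfactory, vomeronasal and taste receptor genes, with Rn45s left out of the total.

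The endothelial score of a library is the mean log2 CPM of the pan-endothelial list. The slope of each gene on this score was fitted with limma with lane and group in the model, and a gene was said to follow the score with a slope above 0.5 and an adjusted p under 0.05. For a member of the list the slope was taken on a score without that gene, but the adjusted p came from the full score. The counts of following genes without single libraries used the full score throughout. No 2 libraries of a group agreed within sampling noise by a chi-square test of their counts. The tests were tried on simulated counts with the means and library sizes of this comparison. These were drawn once, each gene on its own, with the spread that edgeR estimated, which may favour edgeR. Variation shared between genes, such as that of endothelial content, was left out. Of 13534 genes 100 were changed 2-fold and 100 changed 4-fold. edgeR recovered 39 and 88 of them with 4 false calls among 131, DESeq2 1.42.0 recovered 56 and 94 with 39 false among 189, and limma-voom 38 and 90 with 5 false among 133. The slope test recovered 160 of 200 simulated genes with 7 false calls.

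That first set was a fit without a batch term, the library name prefix or the replicate number in place of the lane, the melanocytic score as a covariate, RLE, upper quartile or library size scaling, no filter or a filter of CPM above 1 in at least 5 libraries, DESeq2, limma-voom with quality weights, a false discovery rate of 0.1, and each library left out in turn. Added after seeing the data were the endothelial score, the background reads or the log2 CPM of the Y-linked gene Ddx3y as a covariate, and fits without Rn45s, without lane 2, without the 2 libraries in which Rn45s took over 5% of counts and without the 3 libraries of highest endothelial score, and for the gene lists also the library name prefix.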

Results

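Ribosome-bound mRNA was measured in subcutaneous tumours of 2 mouse melanoma lines, the highly metastatic B16F10 (n = 7 libraries) and the poorly metastatic B16F0 (n = 5), grown for 12 days in C57BL/6 mice. The hosts carried an HA-tagged form of the ribosomal protein Rpl22 that tamoxifen switches on in endothelial cells through Cdh5-driven Cre recombinase, so that precipitation of the tag enriches mRNA bound to ribosomes of blood vessel cells. Gene counts summed to between 5322510 and 20569186 per B16F10 library and between 10753106 and 17381336 per B16F0 library. Each group was spread over 3 sequencing lanes. The labels do not say whether replicates of a group came from separate animals, so p-values measure the spread between these libraries only. The Y-linked gene Ddx3y was at 8.70 to 78.1 CPM in 4 B16F10 and 3 B16F0 libraries, among them all 5 of lane 6, and at up to 0.181 CPM in the other 5. The library names with a prefix also carry a letter F or M, without a stated meaning. Those with M, B16F10 replicate 2 and B16F0 replicate 3, held Ddx3y at 27.7 and 78.1 CPM, and those with F at up to 0.181 CPM. The X-linked gene Xist was at 9.97 to 296 CPM where Ddx3y was low and at 0.451 to 6.40 CPM elsewhere. Libraries of both kinds within a group do not come from the same animal, if the Y-linked reads are those of the host. Sex was not in the main fit. With the level of Ddx3y as a covariate, a fit added after the data were seen, 175 genes were higher and 189 lower in B16F10.

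The precipitates held endothelial transcripts together with abundant transcripts of the pigment cell lineage. Dct, an enzyme of melanin synthesis that melanoma cells express, stood at 6221 ± 1703 CPM (counts scaled to a common library total; SD, n = 7) in B16F10 and 7141 ± 1915 CPM (SD, n = 5) in B16F0. Cdh5, the endothelial cadherin whose promoter drives the Cre, stood at 261 ± 239 and 275 ± 276 CPM in the same groups, and Pecam1, an endothelial adhesion molecule, at 207 ± 187 and 232 ± 239 CPM. Endothelial content varied between libraries far more than between groups. Cdh5 reached 711 and 482 CPM in B16F10 replicates 4 and 5 and 764 CPM in B16F0 replicate 3, against 78.6 to 206 CPM in the other 9 libraries. The mean log2 CPM of 20 pan-endothelial genes was 5.44 ± 1.01 (SD, n = 7) in B16F10 and 5.46 ± 1.02 (SD, n = 5) in B16F0 (exact permutation test, two-sided, p = 0.963 over all libraries and p = 0.944 within lanes). The mean log2 CPM of 20 melanocytic genes was 8.46 ± 0.29 and 8.80 ± 0.24 (exact permutation p = 0.0593, adjusted over 8 library measures 0.237, and p = 0.0833 within lanes). In lanes 1, 2 and 6 it was lower in B16F10 by differences of -0.23, -0.65 and -0.25.

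**Figure D1:**
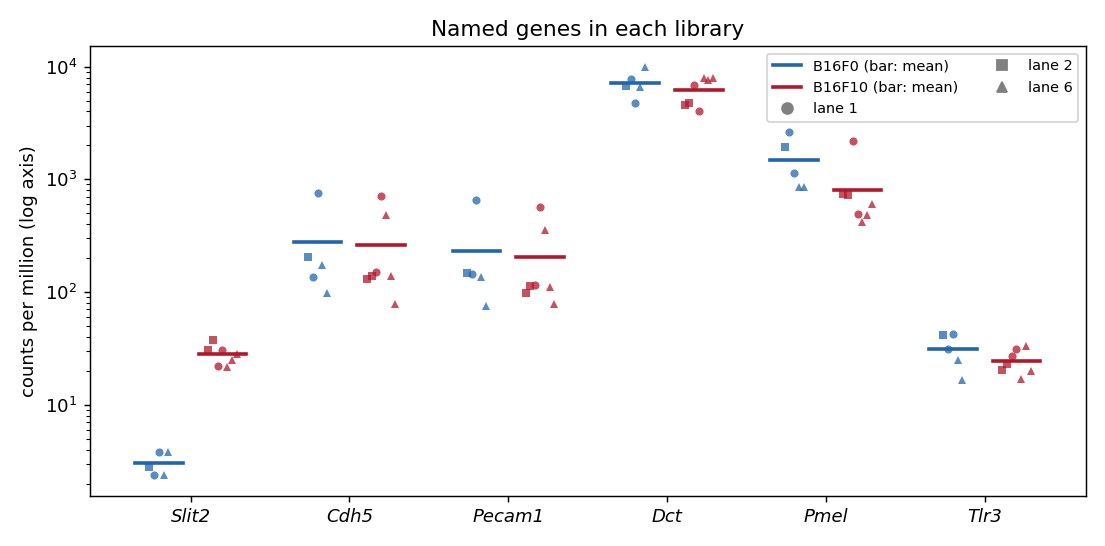
CPM of 6 genes in each of the 12 libraries (log axis), with B16F0 in blue, B16F10 in red, the lane as the marker shape and the group mean as a bar. Slit2 was higher in each of the 7 B16F10 libraries than in any of the 5 B16F0 libraries, while Cdh5 and Pecam1 ranged widely within both groups and Dct lay between 4033 and 9968 CPM.

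Some libraries stood apart in ribosomal RNA precursor reads and in reads of genes silent in most tissues, whose origin was not tested. The ribosomal RNA precursor gene Rn45s took 31.4% of counts in B16F10 replicate 5 (95% Clopper-Pearson interval 31.35 to 31.41) and 8.91% in B16F0 replicate 5 (8.89 to 8.93), and between 0.022% and 1.75% in the other 10. These intervals cover counting error only. Olfactory, vomeronasal and taste receptor genes, 1498 genes taken as a measure of background, summed to 951 and 772 CPM in B16F10 replicates 1 and 2 and to 9.79 CPM in B16F0 replicate 1, the 3 libraries of lane 2. Across all libraries this background was 351 ± 366 CPM (SD, n = 7) in B16F10 and 54.6 ± 48.6 CPM (SD, n = 5) in B16F0 (exact permutation test on log2 values, two-sided, p = 0.0467, adjusted over 8 library measures 0.237). Within lanes the exact permutation p was 0.0722, and the log2 differences were 0.59, 6.45 and 1.21 in lanes 1, 2 and 6.

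The comparison of the tumour types asked which transcripts of the precipitates differ between highly and poorly metastatic tumours. It does not assign a transcript to vessel cells or tumour cells. Slit2, a secreted guidance ligand of the Robo receptors, was among the transcripts with the smallest p, at 28.0 ± 5.69 CPM (SD, n = 7) in B16F10 and 3.03 ± 0.73 CPM (SD, n = 5) in B16F0. The lysosomal cation channel gene Mcoln3 and the mitochondrial protein gene Mgarp had log2 fold changes of 6.51 ± 0.43 (SE) and 4.17 ± 0.24 (SE). The transporter gene Abcc2 and the membrane-bound metalloproteinase gene Mmp16 were lower in B16F10, with log2 fold changes of -4.32 ± 0.18 (SE) and -5.31 ± 0.58 (SE). Mcoln3 fell as the endothelial score rose (slope -0.51, limma adjusted p = 0.0259). The slopes of Slit2, Mgarp, Abcc2 and Mmp16 were 0.045, -0.13, -0.23 and 0.43 (limma adjusted p = 0.853, 0.596, 0.235 and 0.441). In total 375 of 13534 tested genes passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test with the lane in the fit (Benjamini-Hochberg), 176 higher and 199 lower in B16F10. Of these, 136 and 97 changed by more than 2-fold. The direction was shared by all 3 lanes for the 176 higher genes and 198 of the 199 lower genes. The number of genes higher in B16F10 and of genes lower in B16F10 was 136 and 131 without the lane term, 407 and 445 with DESeq2, 104 and 99 without B16F0 replicate 4, and 96 and 81 without the 3 libraries of lane 2. The count of lower genes also fell to 126, 124, 118 and 117 without B16F10 replicate 1, B16F10 replicate 2, B16F0 replicate 1 and B16F0 replicate 5.

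Slit2 lies on chromosome 5 from 47983138 to 48307733 (GRCm38, the build also called mm10). Its log2 fold change was 3.19 ± 0.21 (SE; edgeR adjusted p = 7.1e-06), with all 7 B16F10 libraries above all 5 B16F0 libraries and differences of mean log2 CPM of 3.05, 3.53 and 2.98 in lanes 1, 2 and 6. Within B16F10 it stood at 30.5 and 21.5 CPM in replicates 4 and 5, the libraries of that group with the highest endothelial score, and at 22.2 to 37.9 CPM in the other 5. Its receptor gene Robo1 stood at 85.0 ± 27.7 CPM (SD, n = 7) and 122 ± 35.6 CPM (SD, n = 5), a log2 fold change of -0.49 that did not pass (edgeR adjusted p = 0.352). Robo1 did pass as lower with the library name prefix as a factor (-0.47, edgeR adjusted p = 0.0374), with the melanocytic score as a covariate (-0.92, 0.0135) and without the libraries of highest endothelial score (-0.57, 0.0333). Robo4, an endothelial member of that receptor family, differed by less than the spread between replicates (log2 fold change 0.47, edgeR adjusted p = 0.727). Tlr3, a receptor for double-stranded RNA, was at 24.4 ± 6.15 CPM (SD, n = 7) in B16F10 and 31.4 ± 11.1 CPM (SD, n = 5) in B16F0, a log2 fold change of -0.29 ± 0.22 (SE; edgeR adjusted p = 0.613). Rpl22, whose protein carries the tag, was at 241 ± 44.5 and 301 ± 72.2 CPM (edgeR adjusted p = 0.485).

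The 10 genes with the largest rises that met the naming rule were Slit2, Mcoln3 (chromosome 3, 146117450 to 146141806), Btn2a2, Mgarp (chromosome 3, 51388412 to 51396738), Galnt6, Naalad2, Rltpr, Map7, Ttn and Kif26a. Mcoln3 was at 29.6 ± 11.7 CPM (SD, n = 7) in B16F10 and 0.33 ± 0.34 CPM (SD, n = 5) in B16F0, and Mgarp at 39.7 ± 9.36 and 2.42 ± 1.05 CPM. Btn2a2, a butyrophilin of the immunoglobulin superfamily, had a log2 fold change of 5.05 ± 0.65 (SE) but a level of 9.39 ± 8.98 CPM (SD, n = 7) in B16F10. Galnt6, which starts mucin-type O-glycosylation, had a log2 fold change of 3.60 ± 0.30 (SE), and Naalad2, a glutamate carboxypeptidase, one of 3.22 ± 0.39 (SE). The microtubule-associated protein gene Map7 and the kinesin family gene Kif26a rose by 3.02 ± 0.24 and 2.74 ± 0.48 (SE) on the log2 scale. Ttn, which encodes the giant muscle protein titin, varied widely within B16F10 (191 ± 202 CPM, SD, n = 7, against 18.4 ± 5.11 CPM, SD, n = 5). The call of Kif26a was lost without lane 2 (log2 fold change 2.47, edgeR adjusted p = 0.0665) and without the libraries rich in Rn45s (2.64, 0.0539), and its adjusted p ranged from 2.6e-08 to 0.0992 over 31 settings.

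The 10 genes with the largest falls were Mmp16 (chromosome 4, 17852893 to 18119145), B4galnt4, Abcc2 (chromosome 19, 43782192 to 43840740), Rab29, Hapln4, Fgd2, Phyhipl, L1cam, Mgll and Gja3. Abcc2 had the smallest p, at 2.79 ± 0.91 CPM (SD, n = 7) in B16F10 and 54.6 ± 7.25 CPM (SD, n = 5) in B16F0 (edgeR adjusted p = 1.1e-07). Mgll, the enzyme that breaks down monoacylglycerols, was the most abundant of the 10 and stood at 97.0 ± 26.4 CPM (SD, n = 7) against 596 ± 96.4 CPM (SD, n = 5). The neural cell adhesion gene L1cam was at 4.37 ± 1.64 and 27.9 ± 2.40 CPM, and Gja3, a connexin of gap junctions, at 3.18 ± 1.41 and 15.9 ± 2.68 CPM. Rab29, a small GTPase gene, had a log2 fold change of -3.68 ± 0.35 (SE), and Fgd2, an exchange factor for Cdc42, one of -2.94 ± 0.24 (SE). Hapln4, a hyaluronan-binding matrix protein gene, and Phyhipl fell by 3.65 and 2.84 on the log2 scale. For each of these 10 genes all 7 B16F10 libraries lay below all 5 B16F0 libraries.

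**Figure D2:**
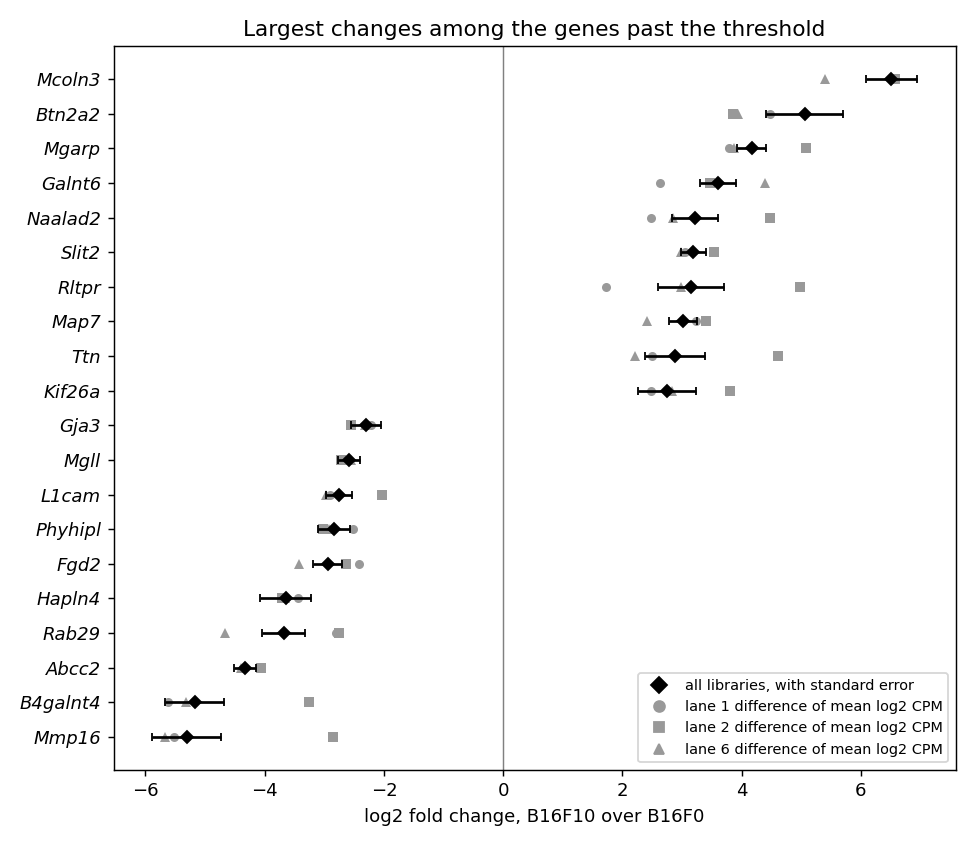
Log2 fold change of B16F10 over B16F0 for the 10 highest and 10 lowest named genes. Black diamonds give the estimate from all 12 libraries with its standard error, and grey markers give the difference of mean log2 CPM within lanes 1, 2 and 6. The estimates ran from -5.31 for Mmp16 to 6.51 for Mcoln3, and the 3 lanes shared each gene's direction because the naming rule required it.

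In the lists of blood vessel signalling few genes passed over all genes. The wide spread of endothelial content limits this test for genes that follow it. Of the 516 genes that followed the endothelial score 0 were called with the lane alone in the fit, against 14.3 expected from the share of all genes. A gene of these lists that did not pass is therefore not shown to be unchanged. Of 16 measured genes of the VEGF receptor and TIE pathway, 1 rose and 1 fell (also 1 and 1 adjusted over the list alone). Nrp2, a co-receptor for VEGF and semaphorins, was at 436 ± 46.1 CPM (SD, n = 7) in B16F10 and 217 ± 50.7 CPM (SD, n = 5) in B16F0, with all 7 B16F10 libraries above all B16F0 libraries. Its log2 fold change was 1.00 ± 0.18 (SE; edgeR adjusted p = 0.00834). Nrp2 did not follow the endothelial score (slope 0.22, limma adjusted p = 0.228), so its rise cannot be assigned to vessel cells. Kdr, the main VEGF receptor of endothelial cells, was at 316 ± 312 and 299 ± 391 CPM and did not pass (edgeR adjusted p = 0.758). Of 32 guidance genes of the semaphorin, plexin, netrin and ephrin families, 1 rose (Nrp2) and 1 fell (Sema3b), against 3 and 3 adjusted over the list alone. Of 11 Slit and Robo genes, Slit2 alone passed over all genes and 2 rose adjusted over the list alone. Slit2 was also the 1 gene of 39 secreted growth factors that rose (2 higher and 2 lower adjusted over the list alone). Among 9 venous genes 1 rose (Nrp2; 2 adjusted over the list alone). None of 13 arterial, 20 tip cell or 20 pan-endothelial genes passed edgeR's test over all genes (1, 0 and 0 higher and none lower adjusted over the list alone). At an unadjusted p under 0.05 the arterial list held 1 higher gene, the tip cell list 1 higher and 1 lower and the pan-endothelial list 0, while DESeq2 called 1, 0 and 0 of these genes and limma-voom 1, 0 and 1. Of 16 Notch pathway genes 0 passed over all genes and 2 rose adjusted over the list alone. Camera did not call that list at the preset (adjusted p = 0.0535) or an estimated correlation (0.98). With the endothelial score in the fit camera called it higher at the preset correlation (adjusted p = 0.00269).

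Adhesion, matrix and metabolic lists also held few called genes. Of 12 measured leukocyte adhesion genes 2 fell, Alcam (log2 fold change -1.23 ± 0.18, SE; edgeR adjusted p = 0.00214) and Cd99l2 (-0.83 ± 0.14, SE; 0.0071), and the same number fell adjusted over the list alone. Cd99l2 was not past the threshold without the lane term (edgeR adjusted p = 0.091) or without lane 2 (0.073), within a range of 7.4e-06 to 0.091 over 31 settings. Ltbp1, which anchors latent TGF-beta in the matrix, was the 1 gene of 25 in the TGF-beta and BMP list that rose (2.08 ± 0.41, SE; edgeR adjusted p = 0.0157), against 4 higher and 1 lower adjusted over the list alone. Its call was lost without B16F0 replicate 4 (2.07, edgeR adjusted p = 0.066), without B16F0 replicate 5 (2.04, 0.0595) and without lane 2 (1.65, 0.0569), within a range of 6.8e-06 to 0.0955. In the hypoxia list 1 of 22 genes rose, Car9, a carbonic anhydrase induced by low oxygen (also 1 adjusted over the list alone). Car9 was at 129 ± 23.7 CPM (SD, n = 7) against 64.8 ± 8.21 CPM (SD, n = 5; edgeR adjusted p = 0.00513), and the list's median log2 fold change was -0.074. In the glycolysis list 1 of 17 rose, the lactate transporter gene Slc16a3 (log2 fold change 0.77, edgeR adjusted p = 0.0103; also 1 adjusted over the list alone), while the list's median was -0.16. The call of Slc16a3 was lost without B16F0 replicate 4 (0.69, edgeR adjusted p = 0.0517) and without the lane term (0.72, 0.176), within a range of 3.2e-05 to 0.38.

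Besides Ltbp1 and Slc16a3, the calls of 6 list members were lost when single libraries were left out. Vegfb, a VEGF family ligand, had a log2 fold change of -0.57 (edgeR adjusted p = 0.0227). The call was lost without any 1 of B16F10 replicates 2, 4 and 7 and B16F0 replicates 1, 2, 4 and 5 (adjusted p from 0.0552 to 0.0869). The guidance gene Sema3b had one of -0.70 (0.0294), lost without any 1 of B16F10 replicates 2, 4, 5 and 6 and B16F0 replicates 1, 2, 4 and 5 (0.0542 to 0.0948). The metalloproteinase gene Adam10 was the 1 of 23 protease and inhibitor genes that fell (-0.72, edgeR adjusted p = 0.0341; also 1 adjusted over the list alone). Its call was lost without any 1 of B16F10 replicates 1, 2, 4, 5, 6 and 7 and B16F0 replicates 1, 4 and 5 (0.0509 to 0.146). F8, encoding coagulation factor VIII, was the 1 of 13 coagulation genes that fell (-1.04, 0.0251; 3 lower adjusted over the list alone), lost without any 1 of B16F10 replicates 1, 2 and 4 and B16F0 replicates 1, 2 and 4 (0.0618 to 0.135). Perp, a desmosomal gene, was the 1 of 3 measured keratinocyte genes that rose (1.42, 0.034; also 1 adjusted over the list alone), lost without any 1 library but B16F10 replicates 3 and 5 (0.0591 to 0.0969). Havcr2 was the 1 of 9 immune checkpoint genes that fell (-0.76, 0.0493; also 1 adjusted over the list alone), lost without each of the 12 libraries (0.0633 to 0.17). Over 31 alternative settings the calls of Vegfb, Sema3b, Adam10, F8, Perp and Havcr2 were lost in 13, 15, 17, 14, 16 and 23.

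No gene of immune sensing or antigen presentation passed. None of 37 interferon response genes, 17 Toll-like receptor and RNA sensing genes, 15 genes of MHC class I or 8 of MHC class II presentation passed in edgeR's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the interferon list held 2 higher and 2 lower genes, the Toll-like receptor list 3 and 2, and both MHC lists 0, while DESeq2 called 0, 1, 0 and 0 genes of these 4 lists and limma-voom 0. The median log2 fold changes of the interferon, Toll-like receptor and MHC class I lists were above 0 (0.26, 0.078 and 0.15) where limma's camera gave a direction to B16F0 (adjusted p = 0.929, 0.884 and 0.877). The same held for the leukocyte adhesion (median 0.13, adjusted p = 0.438), protease (0.0068, 0.808) and immune checkpoint lists (0.18, 0.783).

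In the melanocytic list 2 of 20 genes fell, Oca2, a melanosomal membrane protein gene, and S100b, against 3 lower and 1 higher adjusted over the list alone. Oca2 was at 117 ± 29.8 CPM (SD, n = 7) against 244 ± 47.3 CPM (SD, n = 5; edgeR adjusted p = 0.00379), and S100b had a log2 fold change of -1.17 ± 0.21 (SE; edgeR adjusted p = 0.00847). Without lane 2 the call of S100b was lost (-0.88, edgeR adjusted p = 0.065, within a range of 1.3e-05 to 0.161 over 31 settings). Pmel, a structural protein of melanosomes, was at 811 ± 628 and 1481 ± 783 CPM and did not pass (edgeR adjusted p = 0.249), but passed as lower with the library name prefix as a factor (log2 fold change -0.75, adjusted p = 0.0225) and without B16F10 replicate 3 (-1.23, 0.0289). Set beside other genes with limma's camera at a preset correlation, this list was lower in B16F10 (median log2 fold change -0.28, adjusted p = 0.00349), as was cholesterol biosynthesis (median -0.26, adjusted p = 0.000846). The fibroblast list (median 0.79, adjusted p = 0.000847) and the pericyte and smooth muscle list (median 0.61, adjusted p = 0.000167) were higher. None of the 4 was called with an estimated correlation (adjusted p = 0.98 for each, with unadjusted p = 0.239, 0.241, 0.205 and 0.101 in that order). None of the 51 tested lists passed limma's fry for a shared direction, while 9 passed its test for change in either direction. These included Slit and Robo signalling (adjusted p = 4.8e-06), of whose 11 genes Slit2 alone passed edgeR's test over all genes. Slit2 had an unadjusted edgeR p of 2.0e-09 and the next gene, Robo2, one of 0.0033. The others were the lymphatic, venous, melanocytic, leukocyte adhesion, secreted growth factor, TGF-beta and BMP, hypoxia and NF-kappa-B lists (adjusted p from 0.0283 to 0.0481). No member of the cholesterol, fibroblast or pericyte lists passed edgeR's test over all genes, and 5 lower, 1 higher and 2 higher genes passed adjusted over the list alone. At an unadjusted p under 0.05 the counts were 5, 2 and 3, with DESeq2 5, 1 and 2 and with limma-voom 1, 1 and 1. Hmgcs1, an early enzyme of cholesterol synthesis, stood at 172 ± 62.8 and 312 ± 141 CPM (edgeR adjusted p = 0.0512), and passed as lower in several other settings, such as the name prefix (adjusted p = 0.0284) and DESeq2 (0.00464). Pdgfra, a fibroblast marker, was at 9.73 ± 6.55 and 3.21 ± 1.79 CPM (0.0639), and Notch3, a pericyte marker, at 13.8 ± 13.3 and 3.09 ± 1.33 CPM (0.0941). The difference of the mean log2 CPM between groups was 2.28 for fibroblast and 2.32 for pericyte genes in lane 2, where background reads also differed most, and 0.15 to 0.32 in lanes 1 and 6. Without B16F0 replicate 1, the single B16F0 library of lane 2, none of the 4 lists was called by camera (adjusted p from 0.102 to 0.722), and the melanocytic list was also lost without B16F10 replicate 4 (adjusted p = 0.0518). With the library name prefix in place of the lane, a fit in which the lane 2 libraries share no prefix across groups, the fibroblast (median 0.22, adjusted p = 0.804), pericyte (0.29, 0.393) and cholesterol calls (-0.024, 0.5) were lost. Oxidative phosphorylation (adjusted p = 0.00347) and the unfolded protein response (3.0e-05) were called higher by camera in that fit instead. That fit was run at the preset correlation only. The fibroblast call was also lost without a batch term (adjusted p = 0.335). With background reads as a covariate all 4 calls were lost, with medians of -0.074 for melanocytic, -0.030 for fibroblast, 0.11 for pericyte and 0.10 for cholesterol genes (adjusted p = 0.767, 0.939, 0.794 and 0.819). The number of lists called was 12 without B16F10 replicate 3, 9 without B16F0 replicate 3, 7 without B16F10 replicate 6 and 1 without B16F0 replicate 1.

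Weakly expressed genes leaned to B16F10. Of the 293 tested genes with a mean log2 CPM of 0 or less 4 were called higher and 1 lower, and of the 2362 between 0 and 2 the counts were 49 and 16, with median log2 fold changes of 0.49 and 0.33. Above a mean log2 CPM of 6 the counts were 19 higher and 62 lower among 3658 genes, with a median of -0.06.

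The authors' deposited table gives a comparison of the same groups for 14108 genes, of which 457 passed an adjusted p of 0.05, 210 with positive and 247 with negative values. Over the 13467 genes in both tables the log2 fold changes had a Pearson correlation of 0.996 and a Spearman correlation of 0.995 across genes, which are not independent replicates, and 97.6% shared their direction. A total of 342 genes passed in both with the same direction, of 374 called here and 452 in the authors' deposited table among the shared genes. For Slit2 the authors' deposited table gives a log2 fold change of 3.18 with an adjusted p of 1.37e-06, and for Tlr3 one of -0.29 with 0.588. Among other genes, the authors' deposited table has Pmel (-0.92, adjusted p = 0.0101), Robo2 (1.81, 0.0444) and Hmgcs1 (-0.78, 0.0236) past the threshold, which were not called here.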

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

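The tests of the endothelial score, of the lane 2 libraries and of the rise of abundant stromal genes were chosen after the result was seen. Those of the melanocytic score, of background reads as a covariate, of equal depth and of abundant against other stromal genes were written down first. Of 184 groups of values examined, from 8 library measures and 84 named genes in each tumour type, 14 had a highest or lowest library farther from its group than Dixon's 95% critical value allows, where chance gives about 1 in 20, or 9.2.

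The share of Rn45s stood apart in B16F10 replicate 5 (31.4% against 0.211% to 1.75%, gap over range 0.951) and in B16F0 replicate 5 (8.91% against 0.0218% to 0.282%, 0.971). B16F0 replicate 3 stood apart in Kdr (log2 CPM 9.96 against 6.40 to 7.33, gap over range 0.74), Robo4 (7.42 against 4.75 to 5.21, 0.831), Sema3b (5.63 against 6.03 to 6.14, 0.776) and the mean log2 CPM of the pericyte list (3.33 against 2.39 to 2.63, 0.75). The other B16F0 values were Ak4 in replicate 1 (5.15 against 5.67 to 5.83, gap over range 0.769), Car9 in replicate 2 (6.31 against 5.86 to 5.98, 0.728) and Pdgfra in replicate 4 (-0.86 against 1.42 to 2.25, 0.733). In B16F10 they were F3 in replicate 5 (4.95 against 5.80 to 6.05, 0.773), Pdk1 in replicate 5 (6.92 against 7.46 to 7.80, 0.611), Lgals9 in replicate 7 (3.31 against 4.45 to 5.08, 0.644), Pmel in replicate 3 (11.1 against 8.69 to 9.55, 0.646) and Trpm1 in replicate 4 (8.78 against 9.24 to 9.56, 0.593).

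The called genes did not follow the endothelial content of the libraries. With the lane alone in the fit, following the score hinders a call, so the 375 genes of that fit cannot test their source by themselves. Slopes of genes called with the score in the fit argue against endothelial cells that vary with it as the main source of most such genes. They do not bear on endothelial cells that do not vary with it. The same slope was fitted to both groups, so a gene following the score in B16F10 only would show a lower slope. The median slope was 0.98 for the arterial, 0.99 for the tip cell and 0.56 for the venous list, but -0.056 for the lymphatic list. Single arterial and venous members lay as low as -0.34 and -0.26. With the endothelial score in the fit, where following it does not keep a gene from being called, 524 genes passed, all 375 of the main fit among them. Their median slope on the score was -0.026 (standard error 0.013), and the lowest slope of a pan-endothelial gene 0.49. Without B16F0 replicate 3, B16F10 replicate 4 and B16F10 replicate 5 that median was -0.018, -0.038 and 0.031. The lowest pan-endothelial slopes were then 0.47, 0.43 and 0.47. Of the 516 genes that followed the score 6 passed in that fit, a smaller share than the 3.98% of the other genes (Fisher's exact p = 0.000402). The Fisher p and the standard errors of medians given here take genes of the same 12 libraries as independent, so they overstate the certainty. For Slit2 the slope was 0.045 (95% interval -0.23 to 0.32), but without B16F10 replicate 5 the interval reached 0.54 and overlapped the lowest pan-endothelial slope of 0.47, so an endothelial and another main source of the Slit2 reads cannot be told apart. A source in the tumour cells, which differ between the groups by design, is a candidate explanation for most called genes that stays open. A change in vessels caused by the tumour type stays open, untested, for the rest of them. It also stays open for genes of endothelial cells that do not vary with the score or follow it in B16F10 only. The median slope of the called genes on the melanocytic score was -0.032 (standard error 0.048), below the bound of 0 set in advance against tumour cells but by less than its error, an allowance added after the value was seen. It pools -0.27 (standard error 0.071) for the genes higher in B16F10 and 0.17 (0.060) for the genes lower, against 1.14 for the melanocytic list, and the slope of Slit2 was -0.53 (95% interval -1.28 to 0.22). These rows give the higher genes no sign of following the melanocytic genes, but they decide nothing on tumour cells as the source, because scaling holds the median of all tested genes at -0.0017, so a tumour cell gene outside that list need not rise with the score.

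The lean of weakly expressed genes to B16F10 was not due to unequal depth as the whole cause, since the median log2 fold change of the 2655 tested genes with a mean log2 CPM up to 2 was 0.37 after all libraries were thinned to 5239138 reads, against 0.35 before. With the background reads as a covariate it turned to -0.20, and the counts among these genes went from 53 higher and 17 lower to 33 and 32. Without lane 2 the median was 0.13. Background and tumour type differ together within lane 2, so background reads and a biological difference between the tumours cannot be told apart for these genes.

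The higher level of fibroblast and pericyte genes in B16F10 rested on lane 2, since the median log2 fold change of the 27 members was 0.72 with all libraries and 0.26 without that lane. With the background reads as a covariate it was -0.022, but background and tumour type differ together within lane 2, so this fit also takes away any other difference of those libraries. Reads at the level of the silent genes are too few for the rise of the abundant members, because the 8 with a mean of at least 20 CPM rose in lane 2 by a median of 241 CPM, with 7 of them above the 99th percentile of the levels of chemosensory receptor genes there (2.05 CPM), and the exception, Fbln1, fell by 28.9 CPM. For the lists as a whole the median was 0.80 in the abundant and 0.70 in the other members. This met the outcome set in advance against background reads, but the difference is smaller than its standard error (0.243), an allowance added after the values were seen, so a part of background reads in the weak members stays open. More stromal cells around the B16F10 tumours of that lane, or more of their RNA in those precipitates, may account for the rise but were not tested apart.

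The counts of called genes were larger than in any other split of the libraries that was drawn, while the number of called gene lists was not. The splits were drawn from all 792 without keeping the groups' numbers within each lane. They take the libraries as independent, which the labels do not state. Among 100 splits of the 12 libraries into 7 and 5 with the lane in the fit, 1 (the real one) gave as many genes higher (176, highest other 151) and 1 as many genes lower (199, highest other 100). For the lists 96 of the 100 splits called at least as many as the real one (4, highest other 38). The number of list calls at a preset correlation is therefore not beyond chance. This count does not test the 4 lists one by one.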

How the results depend on the processing

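The fits with the endothelial score, background reads or the level of the Y-linked gene Ddx3y, without Rn45s, without lane 2, without the libraries rich in Rn45s and without those of highest endothelial score, and for the lists the library name prefix, were chosen after seeing the data. Of 34 named called genes 17, Slit2 among them (log2 fold change 2.95 to 3.32), kept their call in all 31 settings, 17 lost it in at least 1 and 0 turned. All 17 that lost it did so with the replicate number as a block, and Car9, Mmp16, Nrp2, Oca2, Rltpr and Ttn only there. No setting turned the direction of any of the 375 called genes it tested (at least 370). The numbers of genes higher in B16F10 and genes lower in B16F10, 176 and 199, became 325 and 305 with the library name prefix, 407 and 445 with DESeq2, 333 and 336 with limma-voom, and 289 and 354 at a false discovery rate of 0.1. They became 96 and 81 without lane 2 and 111 and 125 without the libraries rich in Rn45s. The higher count became 294 with the melanocytic score, and the lower count 131 without a batch term and 132 with library size only. Leaving out 1 library gave 104 to 199 higher and 99 to 247 lower genes, both lowest without B16F0 replicate 4 and highest without B16F10 replicate 3. Of the 375 genes 166 remained without lane 2, 221 with background reads, 261 without a batch term and 375 with DESeq2, the tool with the most false calls on simulated counts. With the replicate number as a block, 30 and 28 genes and 10 lists were called, and Dsp moved to 0.17. Same-numbered libraries had correlations of deviations of -0.27, -0.27, -0.24, -0.29 and 0.32, so the numbers pair nothing. In lane 1, B16F10 replicate 3 and B16F0 replicate 2 share a name prefix and had a correlation of 0.74. B16F10 replicate 4 and B16F0 replicate 3 share another, with 0.55. The lane 1 pairs of unlike prefix had -0.24 (B16F10 replicate 3 with B16F0 replicate 3) and 0.12 (B16F10 replicate 4 with B16F0 replicate 2). The lane term of the main fit pools these prefixes and leaves their difference in the residual. B16F10 replicate 3 also reached 0.67 with B16F0 replicate 1 of another prefix and lane. The lane 6 libraries have no prefix, entered the fit with the prefix as 1 level and had correlations of 0.041 to 0.53 across the groups. With the prefix as a factor Pmel (-0.75) and Hmgcs1 (-0.53) were called lower. All 4 list calls were lost with an estimated correlation, without lane 2 and without B16F0 replicate 1. In the last 2 settings 1 other list, the unfolded protein response, was called, and 12 lists were called without B16F10 replicate 3. With background reads all 4 were lost, the melanocytic median moving to -0.074 and the pericyte median to 0.11, and with the library name prefix the fibroblast (0.22), pericyte (0.29) and cholesterol lists (-0.024). The fibroblast call was also lost without a batch term (adjusted p = 0.335). With Ddx3y the counts were 175 and 189 genes and 5 lists. Robo1, not called in the main fit, was called lower with the library name prefix (-0.47), the melanocytic score (-0.92) and without the libraries of highest endothelial score (-0.57). The overlap with the authors' deposited table was 342 genes and 254 without a batch term. Directions that turned were all of genes not called and of list medians. With the melanocytic score they were Cd276 -0.036, Cdh5 -1.02, Dct 0.024, Jam2 -0.21, Kdr -0.79, Pecam1 -1.01, Pfkm 0.037, Pgam1 0.039, Robo4 -0.59 and Vwf -0.19. With background reads they were Cdh5 -0.36, Jam2 -0.16, Kdr -0.26, Pecam1 -0.41, Pfkm 0.00084, Robo4 -0.20, Rpl22 0.039, Tlr3 0.025, Vwf -0.15, the fibroblast median -0.030 and the cholesterol median 0.10. Cdh5 and Pecam1 also turned without a batch term (-0.074 and -0.17), with limma-voom (-0.19 and -0.067), with the endothelial score (-0.091 and -0.10), without the libraries rich in Rn45s (-0.41 and -0.40, with Dsp 0.14) and without those of highest endothelial score (-0.29 and -0.27). With 1 library left out Cdh5 ran from -0.29 to 0.55, Pecam1 from -0.26 to 0.51 and Dsp from -0.36 to 0.19. Fits without libraries have fewer samples, and the cause of the other changes was not tested. Depth limits genes of few CPM most, since the shallowest library held 5322510 counts.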

Other observations

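The fit with the endothelial score as a covariate was chosen after the results were seen. Few of the genes whose level followed the endothelial content of the libraries passed as different between the tumour types. With the score in the fit 6 of 516 such genes passed (edgeR's quasi-likelihood test, Benjamini-Hochberg), 5 higher and 1 lower in B16F10. The count depends on the slope limit of 0.5. Procr had a slope of 0.498 (limma adjusted p = 0.0402) and was left out by it. In that fit Procr was lower in B16F10 (log2 fold change -1.12, edgeR adjusted p = 0.00259). The number of genes that followed the score was 339 without B16F0 replicate 3, 394 without B16F10 replicate 4 and 653 without B16F10 replicate 5, the 3 libraries of highest score. The immediate early transcription factor gene Egr1 had a log2 fold change of 1.25 (edgeR adjusted p = 0.00304), at 14.3 ± 8.54 CPM (SD, n = 7) in B16F10 and 6.16 ± 4.54 CPM (SD, n = 5) in B16F0. Kif5c, a kinesin heavy chain gene, had one of 1.20 (adjusted p = 0.0228), Ddah2, whose product is a dimethylarginine dimethylaminohydrolase, one of 1.07 (0.0169), the zinc finger gene Zfp423 one of 1.05 (0.0207) and the pseudokinase gene Trib2 one of 0.89 (0.0216). Plau, encoding urokinase, was lower by a log2 fold change of -0.74 (edgeR adjusted p = 0.0026), at 35.7 ± 19.9 CPM (SD, n = 7) and 58.3 ± 31.7 CPM (SD, n = 5). None of the 6 passed with the lane alone in the fit, where the edgeR adjusted p ran from 0.0665 for Egr1 to 0.462 for Plau. With the lane alone 2008 of the 13534 genes had an unadjusted p under 0.05.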
